A study of Mus musculus with 2 samples.

How the data were processed

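Nuclei were isolated from frozen cerebral cortex of wild-type C57BL/6 mice and sequenced with the 10x Genomics Chromium droplet platform, which tags each RNA molecule with a unique molecular identifier (UMI). The labels describe 2 samples, 1 of mice aged 18 months and 1 of mice aged 2 months, each a pool of 3 mice. The series text gives the ages as ranges, 2 to 3 months and 18 to 22 months.

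The deposited matrix holds raw UMI counts per gene and barcode, per the file headers, and 1 matrix holds both samples. Per the file headers the counts were made with Cell Ranger 3.1.0, whereas per the submitters' processing notes Cell Ranger 2.0.1, Seurat 3.1 and R 4.0.2 were used with the genome build mm10. These 2 Cell Ranger versions conflict and the conflict was not settled. The gene annotation, the treatment of intronic reads and the cell calling settings are not given in the sources used here. Each barcode ends in 1 of 2 suffixes, called library 1 and library 2 below. No label ties a suffix to an age, so the matrix counts as 1 sample. No comparison between ages was made, and values of the libraries are set side by side without an age and without a test.

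The comparisons planned between ages, of Gja1, of Cdh5, of gene lists and of the genes with the largest ratios, were therefore not run. What was run is the share of nuclei per class and the level of listed genes per class. Library totals were 58108297 and 60547146 UMIs over 8914 and 8587 barcodes. Nuclei with at least 200 detected genes and at most 5% mitochondrial UMIs were kept. Scrublet, run in scanpy 1.11.5 on each library, marked 0 and 2 barcodes as doublets with its automatic threshold and so had not worked. Nuclei with a doublet score of 0.2 or more were left out instead, a limit set after the scores were seen. It applied to 305 barcodes of library 1 and 332 of library 2. There remained 8286 and 7954 nuclei.

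Counts were scaled to 10000 per nucleus and log-transformed. Listed genes that are not class markers were held out of the 2000 most variable genes, so that clusters were not defined by them. Scaled values, limited at 10, gave 30 principal components, and Leiden clustering at resolution 1 used 15 neighbours and seed 1. A cluster took the class whose markers had the highest mean fraction of their maximum over clusters. It needed at least 3 markers at 0.25 or more of that maximum, a mean of at least 0.33 and a lead of 1.2 times over the next class. A cluster stayed unnamed where another class's markers led its top 10 genes, or where its median UMIs were under 0.5 of the median of kept nuclei with no own marker among those genes. The markers were fixed before the data were examined; these thresholds, and the merging of pericytes with smooth muscle, were set after the clusters were seen. The low-UMI limit kept 2 clusters out of the excitatory and fibroblast classes: 1271 nuclei (551 in library 1, 720 in library 2) and 191 nuclei (91 and 100). Class names stand for nuclei that are like that class by its markers.

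UMIs were summed over the nuclei of a class and library and given as CPM, counts scaled to the class sum. Intervals are exact 95% Poisson intervals for CPM and exact 95% Clopper-Pearson intervals for shares. They cover counting error only, since nuclei are not replicates. Shares of nuclei with a UMI were also taken after thinning each nucleus to 1500 UMIs, with shallower nuclei left out. The 10 classes with at least 50 nuclei in each library were compared. For each gene list, members with at least 20 UMIs over these classes were counted where their highest CPM fell in the class the list is about. The median log2 ratio of that class to the mean of the other classes, with 1 CPM added, was placed among 10000 random lists matched within 100 ranks of mean CPM, as a description of these libraries. List members that are class markers were left out.

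The genes named are Gja1 and Cdh5 in every class and, since ages could not be mapped, the 4 members of each list with the highest CPM in any class. These members are given in the class with their highest CPM over both libraries together. That class need not be the highest in each library. Any other gene is named as chosen after its values were seen. Positions are from GENCODE vM21, which uses the build mm10; the annotation behind the counts may differ. Cldn25 and Clec7a were not analysed here. The level of 1 further gene that the rule names is not reported here.

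The calculations were tested on simulated counts. Of 100 genes raised 2-fold in 1 simulated class, 100 and 98 had their highest level there in the 2 simulated libraries. Of 100 raised 4-fold, 100 did in each. The raised genes were drawn only from genes above 20 CPM over all barcodes, and the simulated class sums were not those of the data. This recovery therefore does not show how list members near the minimum of 20 UMIs would fare. The Poisson interval held the true level for 96.7% and 96.6% of 176791 values. The simulated sums were drawn directly from the known levels, without differences between nuclei. This checks the calculation only and does not show how often the intervals hold in these data. Alternatives were: doublets kept, no mitochondrial limit, a limit of 1%, a minimum of 500 genes, resolutions 0.5 and 2, nuclei weighted equally and thinned nuclei. A doublet score limit of 0.15 and a low-UMI limit of 0.33 of the median were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0 were used.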

Results

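Single-nucleus RNA profiles of mouse cerebral cortex were collected to follow transcripts related to the blood-brain barrier across cell types in natural ageing. The 2 samples, 1 per age, were deposited as 1 matrix of 30905 genes and 17501 barcodes with 118655443 UMIs. The labels do not say which barcode suffix belongs to which age, so no difference between ages is reported. Library 1 had a median of 5992 UMIs and 2543 genes per barcode, and library 2 a median of 6450 UMIs and 2456 genes. There are no replicates, and all intervals cover counting error only.

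Both libraries held neurons, glia and the cells of the vessel wall. Excitatory neurons made up 49.9% of kept nuclei in library 1 (4135 of 8286, 95% interval 48.8 to 51.0) and 52.5% in library 2 (4174 of 7954, 51.4 to 53.6). This class pools 10 clusters, and cluster 6, led by Glis3, Prox1 and Tspan18, made up 4.31% and 2.60% of the libraries. The brain region that each cluster came from was not assigned. Nuclei with striatal markers were present, so the shares, that of excitatory neurons among them, may include nuclei from outside the cortex. Inhibitory neurons were 8.65% and 7.68%, and nuclei with markers of striatal projection neurons 4.72% and 2.93%. Oligodendrocytes were 10.8% (10.1 to 11.5) and 5.34% (4.86 to 5.86), astrocytes 5.24% and 5.29%, microglia 2.61% and 2.68%, and oligodendrocyte precursors 1.59% and 1.97%. Endothelial nuclei were 1.89% (157 nuclei, 1.61 to 2.21) and 3.70% (294 nuclei, 3.29 to 4.13). Pericytes with smooth muscle were 0.797% and 1.04%, and fibroblasts 1.27% and 1.37%. Newly formed oligodendrocytes numbered 3 and 42. Unnamed clusters held 12.2% and 14.5%. The fibroblast share was 2.37% and 2.63% when the low-UMI limit was 0.33 of the median and 2.46% and 2.86% with doublets kept, and without a mitochondrial limit no fibroblast class was named. A mitochondrial limit of 1% left no endothelial or fibroblast class and took astrocytes to 2.73% and 1.88%, oligodendrocytes to 2.68% and 1.92%, microglia to 0.580% and 0.476% and pericytes with smooth muscle to 0.290% and 0.454%.

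**Figure D1:**
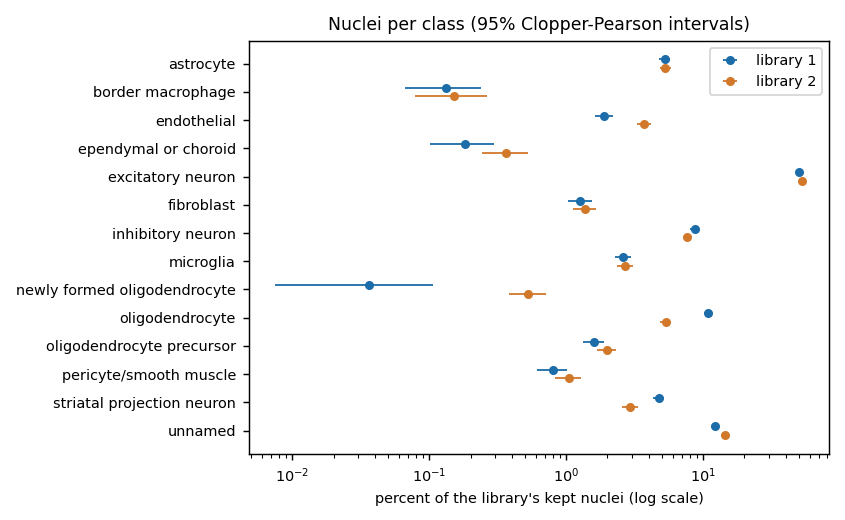
Percent of each library's kept nuclei per class on a log axis, for library 1 (blue) and library 2 (orange); bars are exact 95% Clopper-Pearson intervals. Excitatory neurons made up 49.9% and 52.5%, and endothelial nuclei 1.89% and 3.70%.

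Gja1 encodes connexin 43, a gap junction protein, and lies on chromosome 10 from 56377330 to 56402513 (mm10). Among the 10 compared classes its transcripts were most abundant in astrocytes, at 322 CPM (373 UMIs, 95% interval 290 to 357) in library 1 and 378 CPM (486 UMIs, 345 to 413) in library 2. Unnamed cluster 29, outside these classes, held 96.6 CPM (63.7 to 141) and 450 CPM (392 to 515). Fibroblasts followed astrocytes at 177 CPM (139 to 222) and 199 CPM (161 to 242), and the latter was 322 CPM with the low-UMI limit of 0.33. Endothelial nuclei held 36.9 CPM (21 UMIs, 22.9 to 56.4) and 37.8 CPM (41 UMIs, 27.2 to 51.3). These levels lay within the counting intervals of microglia, at 24.6 CPM (12.7 to 43.0) and 31.8 CPM (18.5 to 50.9). Oligodendrocytes held 37.5 and 32.2 CPM, and oligodendrocyte precursors 22.6 CPM in each library. Pericytes with smooth muscle held 45.8 and 21.8 CPM, excitatory neurons 6.79 and 9.39, inhibitory neurons 8.08 and 10.95, and striatal projection neurons 8.03 and 10.4. After thinning, 4.83% (1.96 to 9.69) and 6.76% (4.12 to 10.4) of endothelial nuclei had a Gja1 UMI, beside 4.19% (1.70 to 8.45) and 5.85% (3.06 to 10.0) of microglia, a class that should lack it. Microglia held more neuronal synaptic transcripts than endothelial nuclei, 2.55% and 2.38% of UMIs against 1.38% and 1.21%. The 2 classes may therefore not carry equal amounts of foreign RNA. Without thinning the shares with Gja1 were 10.2% and 11.9% in endothelial nuclei and 5.56% and 7.98% in microglia, at median depths of 2490 and 2624 UMIs and of 1689.5 and 1985 UMIs. These values did not set endothelial nuclei apart from microglia at this depth. At the mitochondrial limit of 1% the microglial level of library 2 was 6.05 CPM, from a class of 46 nuclei over both libraries. That limit left no endothelial class to compare, so the lower level decides nothing. The endothelial levels lay above those of the 3 neuron classes with intervals apart in both libraries. Neuron nuclei were deeper, however, with medians of 7863 and 8485 UMIs in excitatory neurons, so they are not a depth-matched background. Unnamed cluster 3, at a median of 2256 UMIs, held Gja1 at 50.7 CPM (38.6 to 65.4) and 66.8 CPM (55.1 to 80.3). Neither level lay below the endothelial one. The endothelial to astrocyte ratio of Gja1, 0.115 (0.0701 to 0.178) and 0.100 (0.0709 to 0.138), lay above the ratios of all 7 astrocyte markers, whose highest were 0.0669 and 0.0757, with the interval apart from the highest in library 1 only. Whether endothelial nuclei express Gja1 was therefore not settled.

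Cdh5 encodes VE-cadherin, the adherens junction protein of endothelium, and lies on chromosome 8 from 104101625 to 104144511. Endothelial nuclei held 258 CPM of Cdh5 (147 UMIs, 218 to 304) and 173 CPM (187 UMIs, 149 to 199). Fibroblasts held 99.3 CPM (71.3 to 135) and 86.0 CPM (62.0 to 116). In astrocytes Cdh5 stood at 0.864 and 7.0 CPM, in excitatory neurons at 0.665 and 1.15, in inhibitory neurons at 0.859 and 2.58, and in striatal projection neurons at 1.10 and 1.22. Microglia held 2.05 and 5.61 CPM of Cdh5, oligodendrocytes 3.97 and 3.39, precursors 1.89 and 1.74, and pericytes with smooth muscle 5.73 and 8.70.

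Among 12 measured connexins and pannexins, 0 and 2 had their highest level in endothelial nuclei, 1 and 2 in astrocytes, and 3 in oligodendrocytes in each library. The endothelial count of library 1 was 1 with doublets kept, a doublet score limit of 0.15, equal weights or thinning and 2 without a mitochondrial limit, and that of library 2 was 1 with doublets kept. The astrocyte counts ran from 1 to 2 and from 1 to 3 over the alternatives. The list's median lay low among random lists, at the 0.25 and 3.02 percentile in endothelial nuclei, 0.61 and 3.06 in astrocytes and 2.79 and 1.41 in oligodendrocytes. Gjc1, the gene of connexin 45, was highest in pericytes with smooth muscle at 298 CPM (222 to 390) and 252 CPM (192 to 326), followed by endothelial nuclei at 206 CPM (170.1 to 247) and 137 CPM (115 to 160.5). The endothelial Gjc1 levels lay above those of Gja1 with intervals apart in both libraries. Pericyte RNA as a source of the endothelial Gjc1 was not tested. Gjc3 stood at 271 and 243 CPM in oligodendrocytes and at 211 and 93.8 CPM in their precursors. Gjb6, the gene of connexin 30, stood at 220 and 129 CPM in fibroblasts and 118 and 66.1 CPM in astrocytes.

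**Figure D2:**
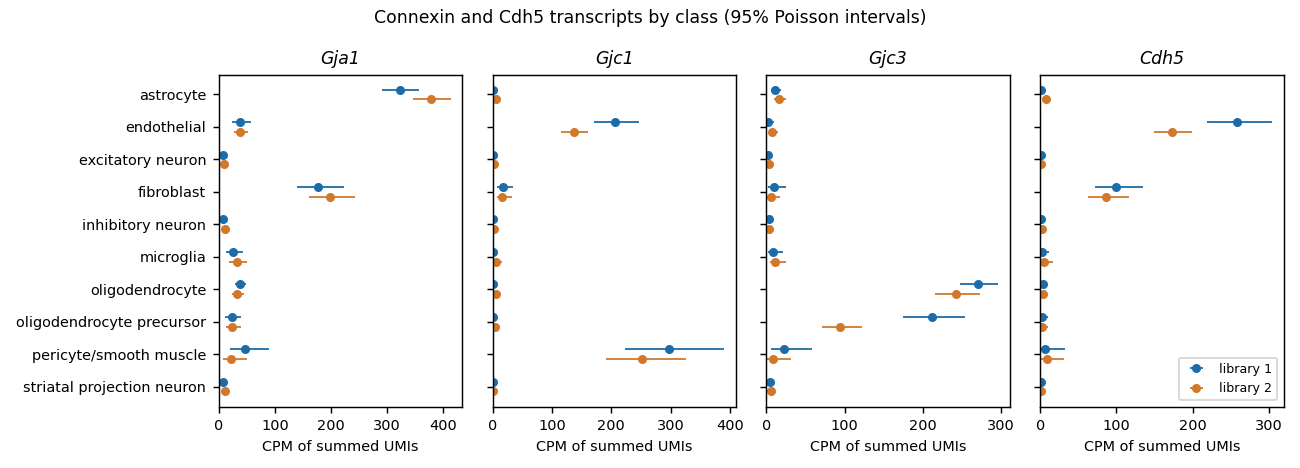
CPM of summed UMIs (x axis, linear from 0) of Gja1, Gjc1, Gjc3 and Cdh5 in the 10 compared classes, for library 1 (blue) and library 2 (orange); bars are exact 95% Poisson intervals. Gja1 peaks in astrocytes at 322 and 378 CPM and Cdh5 in endothelial nuclei at 258 and 173 CPM.

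Junction and transport genes of the barrier were concentrated in endothelial nuclei. Of 17 tight and adherens junction genes, 11 and 10 were highest there, 10 of them in both libraries, and the list's median log2 ratio was 1.79 and 1.76. Tjp1, a scaffold of tight junctions, stood at 1322 and 1800 CPM, Cldn5, a tight junction claudin, at 673 and 758, and Ctnna1 at 294 in each library; Afdn was highest in fibroblasts at 417 and 426. Of 24 transporters and receptors, 19 and 20 were highest in endothelial nuclei, 19 in both, with a median log2 ratio of 2.71 and 2.82. Slco1a4, an organic anion transporter, stood at 1653 and 2649 CPM, Slc2a1, the glucose transporter GLUT1, at 1489 and 1123, Slc6a6 at 1568 and 1170, and Slco1c1 at 889.5 and 1175. Each of these medians lay above all 10000 matched random lists.

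Of 13 transcytosis and permeability genes, 9 and 8 were highest in endothelial nuclei, among them Eng at 383 and 443 CPM and Vwf at 294 and 296 CPM. The medians of this list, of the Wnt list and of the basement membrane list in endothelial nuclei, and of the last also in pericytes with smooth muscle, lay above all 10000 random lists in each library. Angpt1 stood at 126 and 292 CPM in pericytes with smooth muscle, and Vegfa at 235 and 151 CPM in astrocytes. Of 16 genes of endothelial Wnt signalling, 13 and 12 were highest in endothelial nuclei, including Lef1 at 933 and 994 CPM and Reck at 146 and 157. Apcdd1 stood at 98.4 and 186 CPM there, its highest class in library 2 only. Lrp6 stood at 184 and 205 CPM in fibroblasts, but its highest class in library 1 was endothelial nuclei. Of 15 basement membrane genes, 8 and 7 were highest in endothelial nuclei and 2 and 5 in pericytes with smooth muscle; the endothelial count of library 2 was 4 after thinning, and the pericyte counts were 13 and 14 at the mitochondrial limit of 1%, which left no endothelial class, and 5 in library 1 without a limit. Fn1 stood at 320 and 558 CPM in endothelial nuclei, Lamc1 at 401 and 422 CPM in pericytes with smooth muscle, and Lama2 at 1325 and 733 CPM and Lama1 at 637 and 574 CPM in fibroblasts.

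Genes of NAD metabolism were spread over several classes. Of 23 measured members, 1 and 3 were highest in endothelial nuclei, 5 and 2 in astrocytes and 0 in excitatory neurons in each library. Over the alternatives that gave a value, the endothelial counts ran from 0 to 2 and from 2 to 7. The astrocyte counts ran from 2 to 6 and from 1 to 8, and the excitatory counts from 0 to 2 and from 0 to 1. The astrocyte count of 8 and the excitatory count of 2 came at the mitochondrial limit of 1%, which left no endothelial or fibroblast class. The endothelial count of 7 came without a mitochondrial limit, where no fibroblast class was named. The list's median lay at the 26.3 and 86.4 percentile of random lists in endothelial nuclei, at 97.0 and 97.4 in astrocytes and at 82.2 and 39.3 in excitatory neurons. Nampt, the rate-limiting enzyme of NAD salvage, stood at 79.1 CPM (57.7 to 106) and 137 CPM (115 to 160.5) in endothelial nuclei. These were its highest class in library 2 only. Nmnat2 stood at 574 and 495 CPM in oligodendrocyte precursors, Nadk2 at 191 and 281 CPM in fibroblasts and Sirt2 at 119 and 151 CPM in oligodendrocytes.

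Interferon and antigen presentation genes were highest in endothelial nuclei for 14 of 19 members in each library, 12 of them in both. In microglia 0 and 1 were highest, from 0 to 3 and from 0 to 2 over the alternatives. The 3 came at the mitochondrial limit of 1%, which left no endothelial or fibroblast class and 46 microglia over both libraries. Members highest in endothelial nuclei then fall to other classes. The list's median in endothelial nuclei lay above all 10000 random lists, and in microglia at the 0.19 and 7.69 percentile. H2-D1 stood at 237 and 137 CPM in endothelial nuclei, H2-K1 at 223 and 124, B2m at 253 and 92.3 and Ifitm3 at 172 and 62.8. Of 10 activation genes, 5 and 6 were highest there (8 in library 1 without a mitochondrial limit), with Cxcl12 at 582 and 426 CPM and Il1r1 at 505 and 399.7; Il6ra stood at 224 and 166 CPM and Nfkb1 at 164 and 187 CPM in microglia. The median of the activation list also lay above all random lists. Of 9 senescence genes, 4 and 3 were highest in endothelial nuclei (5 in library 2 without a mitochondrial limit), and the list's median lay at the 96.85 and 86.5 percentile. Cdkn1a, the gene of the cell cycle inhibitor p21, stood at 185 CPM (151 to 223) and 34.2 CPM (24 to 47.1) there, and Hmgb1 at 156 and 93.2. Rb1 stood at 233 and 288 CPM in astrocytes. Endothelial nuclei also had a high mitochondrial share, 2.51% and 2.47% of their UMIs, with mt-Atp6 at 5606 and 5470.1 CPM, mt-Co3 at 4543 and 4466, mt-Co2 at 3899 and 3765 and mt-Co1 at 3399.98 and 2888.

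Of 12 endfoot genes, 6 and 7 were highest in astrocytes, with a median above all random lists and Dtna at 1693 and 1738 CPM; Dmd stood at 3768 and 3590 CPM in pericytes with smooth muscle and Sgcd at 2304 and 2028 CPM in oligodendrocyte precursors. Of 11 reactive astrocyte genes, 3 and 5 were highest in astrocytes (3 in library 2 after thinning), with Gfap at 159 and 119 CPM; the list's median log2 ratio in astrocytes was -0.79 and 0.09, at the 2.97 and 79.3 percentile. Cp stood at 964 and 1018 CPM in fibroblasts, and Osmr at 137 and 126 and Vim at 151 and 81.2 in endothelial nuclei. Of 12 genes of activated microglia, 4 and 6 were highest in microglia (2 in each library at the mitochondrial limit of 1%), with Trem2 at 65.7 and 146 CPM and Ctsb at 191 and 262, and the list's median lay at the 98.2 percentile in library 1 and above all random lists in library 2; Apoe stood at 1729 and 2720 CPM in astrocytes and Cd9 at 109 and 182 CPM in oligodendrocyte precursors. Of 9 myelin and oligodendrocyte genes, 6 were highest in oligodendrocytes in each library, with medians above all random lists. At Leiden resolution 2 this class split into a cluster of 874 nuclei of library 1 and 64 of library 2 and a cluster of 21 and 361, so its levels come from largely separate clusters in the 2 libraries. Cldn11 stood at 280 and 895 CPM there, Anln at 403 and 217 and Il33 at 329 and 82.3, and Apod at 921 and 1131 CPM in fibroblasts.

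None of 14 immediate early or 8 heat shock genes was highest in excitatory neurons in either library, and their medians there lay at the 0.26 and 0.20 percentile and at the 1.62 and 2.09 percentile. Egr1 stood at 557 and 385 CPM, Btg2 at 274 and 172 and Junb at 136 and 86.0 in fibroblasts, and Dusp1 at 169 and 113 in endothelial nuclei. Hspa8 stood at 399.7 and 255 CPM and Hsp90aa1 at 124 and 98.4 in oligodendrocytes, Hsp90ab1 at 263 and 265 in pericytes with smooth muscle and Hsph1 at 117 and 118 in microglia. Unnamed cluster 3, outside these classes and closest to excitatory neurons, exceeded these levels in library 1. It held Hspa8 at 555 CPM, Hsp90ab1 at 385, Hsph1 at 157 and Hsp90aa1 at 140. Its Egr1, Btg2, Junb and Dusp1 levels in library 1 lay below those given above.

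Neuronal synaptic transcripts took 4.12% and 4.44% of UMIs in excitatory neurons, and also 1.38% and 1.21% in endothelial nuclei and 2.55% and 2.38% in microglia. Kcnip4 stood at 9570.5 and 12357 CPM and Nrg3 at 6019 and 7343 in excitatory neurons, Meg3 at 11317 and 9139.6 in inhibitory neurons and Rbfox1 at 10798 and 14794 in striatal projection neurons. Transcripts of 4 Y-linked genes stood at 410 and 433 CPM in endothelial nuclei and 291 and 246 CPM in excitatory neurons, while Xist had 16 and 13 UMIs in the whole libraries. Uty stood at 199 and 234 CPM, Ddx3y at 126 and 121 and Kdm5d at 75.1 and 43.0 in fibroblasts, and Eif2s3y at 128 and 95.03 in oligodendrocytes.

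Some levels moved beyond their intervals and by over 1.5 times with the processing. With doublets kept, fibroblasts held Lama1 at 337 and 263 CPM, Cp at 556 and 525, Apod at 555 and 673, Egr1 at 327 and 213, Btg2 at 138 and 111 and Nadk2 at 111 and 146, and in library 1 Gjb6 at 143 and Junb at 79.9. With the low-UMI limit of 0.33 they held Lama1 at 380.0 and 309 CPM and Cp at 621 and 588, in library 1 Btg2 at 181 and in library 2 Egr1 at 244 and Nadk2 at 172. At the mitochondrial limit of 1%, microglia held Trem2 at 12.5 and 60.5 CPM, Ctsb at 99.8 and 133, Il6ra at 74.9 and 30.3 and Nfkb1 at 62.4 and 90.8, and in library 1 Hsph1 at 56.1. At that limit Apoe in astrocytes stood at 1151 and 1747 CPM and Gfap at 79.2 in library 1, oligodendrocytes held Gja1 at 16.02 and 18.6 CPM and in library 2 Anln at 142 and Il33 at 40.2, and precursors held Sgcd at 1098 in library 2. Pericytes with smooth muscle held Angpt1 at 274 and 572 CPM at that limit and at 33.5 and 72.0 without one. Their Dmd level was 7339 CPM in library 1 at that limit and 1750.2 and 1597 without one, and in library 1 Lamc1 stood at 219 and Hsp90ab1 at 137 at that limit. In library 1, endothelial Ifitm3 stood at 113 CPM with equal weights and 106 after thinning, and Hmgb1 at 87.4 after thinning. Trem2 in microglia of library 1 stood at 99.8 CPM after thinning, Cd9 in precursors of library 2 at 282 at resolution 0.5, and Sirt2 in oligodendrocytes of library 2 at 96.4 with doublets kept. Gja1 in striatal projection neurons of library 1 stood at 13.7 CPM after thinning. Cdh5 was 0 in pericytes with smooth muscle of each library after thinning and at the mitochondrial limit of 1%, and in library 1 also without a limit. It was 0 in precursors of library 1 after thinning and of library 2 at the limit of 1%, and in library 2 also in striatal projection neurons after thinning and in microglia and oligodendrocytes at the limit of 1%. After thinning it stood at 5.46 CPM in inhibitory neurons of library 2 and at 3.42 CPM in striatal projection neurons of library 1.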

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

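The tests on Gja1, on Cdh5, on doublets and on the mitochondrial share were chosen after the levels they bear on had been seen; the test on Malat1 was set before its level was seen, for damaged nuclei and cytoplasmic fragments together, and was limited to fragments afterwards. No biological explanation was tested, since the ages could not be assigned to nuclei.

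The 7 unnamed clusters entered no comparison, and some held UMIs of Gja1 or Cdh5 above the limit that a count of 0 allows. In cluster 3 Gja1 stood at 50.7 and 66.8 CPM and Cdh5 at 4.30 and 9.96 CPM in library 1 and library 2. In cluster 11 Gja1 stood at 13.1 and 9.50 CPM and Cdh5 at 6.78 CPM in library 2. In cluster 22 Gja1 stood at 5.52 and 6.35 CPM and Cdh5 at 3.63 CPM in library 2. In cluster 28 Gja1 stood at 8.23 CPM in library 1. Cluster 29, led by Bnc2, Slc47a1 and Adamtsl3 and closest to fibroblasts, held Gja1 at 96.6 CPM (27 UMIs, 63.7 to 141) and 450 CPM (212 UMIs, 392 to 515), and Cdh5 at 50.1 and 97.7 CPM.

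The Gja1 UMIs of endothelial nuclei were weighed against RNA of astrocytes as their whole source. A single source would keep its genes near 1 ratio, and the endothelial to astrocyte CPM ratio of Gja1 was 0.115 (0.0701 to 0.178) in library 1 and 0.100 (0.0709 to 0.138) in library 2. The 7 astrocyte markers had median ratios of 0.0258 and 0.0321 and highest ratios of 0.0669 and 0.0757, all below that of Gja1. The markers did not share 1 ratio themselves: Gpc5 stood at 0.0147 (0.0115 to 0.0185) and 0.0170 (0.0144 to 0.0199), and Slc1a2 at 0.0669 (0.0593 to 0.0752) and 0.0757 (0.0700 to 0.0818). The interval of Gja1 lay above the highest marker ratio in library 1 but held it in library 2, so astrocyte RNA cannot be told apart from another source.

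The Cdh5 UMIs of fibroblast nuclei were weighed against endothelial RNA in the same way. The fibroblast to endothelial ratio of Cdh5 was 0.384 (0.265 to 0.547) and 0.498 (0.348 to 0.700), whereas 9 endothelial markers ran from 0, for Egfl7, to 0.139 (0.0926 to 0.201) for Pecam1 in library 1 and 0.125 (0.0707 to 0.207) for Ly6c1 in library 2. These markers did not share 1 ratio either. The interval of Cdh5 lay above all of their ratios in each library. Class markers could enter the clustering and named the classes, whereas Cdh5 was held out of the clustering. Fibroblast nuclei may thus be selected for low levels of the markers but not of Cdh5. The comparison therefore cannot decide whether endothelial RNA was the whole source of this Cdh5 signal or a part of it.

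The largest unnamed cluster, number 3 with 1271 nuclei, was led by Gm29260, Tmsb4x, Aldoa and Ubb, with Tubb5, Ppia and Atp5g3 also among its top 10 genes. Its median of 2.30% mitochondrial UMIs lay above the 0.510% to 0.923% of the excitatory clusters but within the 1.26% to 2.32% of 7 named clusters of other classes that also lay under the low-UMI limit, so damaged nuclei, or nuclei with cytoplasm attached, cannot be told apart. Cytoplasmic fragments in place of nuclei would hold less of the nuclear RNA Malat1. Malat1 stood at 29139 and 39698 CPM in the cluster and at 18935 and 34803 CPM in excitatory neurons. With excitatory nuclei as the only yardstick, this argues against such fragments. No class of similarly few UMIs was set beside the cluster for Malat1. Doublets cannot be told apart: the median of 2256 UMIs, below 6250 for all kept nuclei, was fixed by the low-UMI rule that left the cluster unnamed. What sets the cluster apart stays open.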

How the results depend on the processing

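The alternatives between ages, and those of scaling, pseudocount and UMI minimum that belong to them, were not run, since no nucleus could be assigned an age. No paired analysis was possible because the result comes from no test and the barcodes carry no sample. A minimum of 500 genes removed no nucleus and so tested nothing. At Leiden resolution 2 the class shares, the list counts and the levels of Gja1 in astrocytes, endothelial nuclei and fibroblasts and of Cdh5 in endothelial nuclei and fibroblasts, 80 results in all, stayed within their intervals or within 1.5 times, but levels of 4 further results, those of Kcnip4 and Nrg3 in excitatory neurons of both libraries, moved. A limit of 1% mitochondrial UMIs left no endothelial, fibroblast, border macrophage or newly formed oligodendrocyte class, so 36 results had no value; without any mitochondrial limit no fibroblast class was named, so list members were compared over fewer classes. With doublets kept, and at resolution 0.5, no border macrophages or newly formed oligodendrocytes were named. The doublet score limit of 0.15 and the low-UMI limit were chosen after seeing the data. Among 178 further levels, those of other named genes and of Gja1 and Cdh5 in the other classes, 73 moved with doublets kept (3 higher, 70 lower), 54 with nuclei thinned (12 higher, 42 lower), 47 with equal weights (8 higher, 39 lower), 21 with the low-UMI limit of 0.33 (2 higher, 19 lower), 12 at resolution 0.5 (3 higher, 9 lower), 4 at resolution 2 (2 higher, 2 lower) and 3 with the doublet score limit of 0.15 (2 higher, 1 lower). Of 92 with a value at the 1% limit 55 moved (16 higher, 39 lower), and of 150 without a mitochondrial limit 22 moved (14 higher, 8 lower). The moved values among the 80 results are given for library 1, then library 2; the cause was not tested. With doublets kept, shares were 48.1% and 50.7% for excitatory neuron nuclei, 2.46% and 2.86% for fibroblast nuclei, 3.18% and 3.17% for microglia nuclei, 4.44% for oligodendrocyte nuclei (library 2). Levels were 260.1 CPM and 295 CPM for Gja1 in astrocyte nuclei, 137 CPM and 271 CPM for Gja1 in fibroblast nuclei, 147 CPM for Cdh5 in endothelial nuclei (library 2), 66.8 CPM for Cdh5 in fibroblast nuclei (library 1). Counts of members highest in their class were 1 and 1 for connexins and pannexins genes in endothelial nuclei, 0 for NAD metabolism genes in endothelial nuclei (library 1), 1 for connexins and pannexins genes in astrocyte nuclei (library 2), 0 for interferon response and antigen presentation genes in microglia nuclei (library 2). Without a mitochondrial limit, shares were 0.453% and 0.945% for ependymal or choroid nuclei, 48.5% and 50.3% for excitatory neuron nuclei, 0.616% and 0.751% for pericyte/smooth muscle nuclei. Counts of members highest in their class were 2 for connexins and pannexins genes in endothelial nuclei (library 1), 2 for connexins and pannexins genes in astrocyte nuclei (library 1), 8 for endothelial activation genes in endothelial nuclei (library 1), 5 for vascular basement membrane genes in pericyte/smooth muscle nuclei (library 1), 2 and 7 for NAD metabolism genes in endothelial nuclei, 5 for senescence genes in endothelial nuclei (library 2), 0 for interferon response and antigen presentation genes in microglia nuclei (library 2). With a mitochondrial limit of 1%, shares were 2.73% and 1.88% for astrocyte nuclei, 0.173% for ependymal or choroid nuclei (library 2), 58.6% and 63.3% for excitatory neuron nuclei, 11.4% and 9.73% for inhibitory neuron nuclei, 0.580% and 0.476% for microglia nuclei, 2.68% and 1.92% for oligodendrocyte nuclei, 0.290% and 0.454% for pericyte/smooth muscle nuclei, 5.95% and 3.55% for striatal projection neuron nuclei. Levels were 275 CPM and 281 CPM for Gja1 in astrocyte nuclei. Counts of members highest in their class were 2 for connexins and pannexins genes in astrocyte nuclei (library 1), 13 and 14 for vascular basement membrane genes in pericyte/smooth muscle nuclei, 3 and 8 for NAD metabolism genes in astrocyte nuclei, 2 for NAD metabolism genes in excitatory neuron nuclei (library 1), 3 and 2 for interferon response and antigen presentation genes in microglia nuclei, 2 and 2 for activated microglia genes in microglia nuclei. With a doublet score limit of 0.15, counts of members highest in their class were 1 for connexins and pannexins genes in endothelial nuclei (library 1), 3 for NAD metabolism genes in astrocyte nuclei (library 1), 0 for interferon response and antigen presentation genes in microglia nuclei (library 2). At Leiden resolution 0.5, shares were 52.2% and 54.3% for excitatory neuron nuclei, 2.49% for oligodendrocyte precursor nuclei (library 2). Counts of members highest in their class were 2 for NAD metabolism genes in endothelial nuclei (library 1). With a low-UMI limit of 0.33, shares were 56.6% and 61.5% for excitatory neuron nuclei, 2.37% and 2.63% for fibroblast nuclei. Levels were 322 CPM for Gja1 in fibroblast nuclei (library 2). With each nucleus weighted equally, levels were 149 CPM for Gja1 in fibroblast nuclei (library 2), 190.1 CPM for Cdh5 in endothelial nuclei (library 1). Counts of members highest in their class were 1 for connexins and pannexins genes in endothelial nuclei (library 1), 2 for NAD metabolism genes in endothelial nuclei (library 1), 2 and 1 for NAD metabolism genes in astrocyte nuclei, 1 for connexins and pannexins genes in astrocyte nuclei (library 2), 2 for interferon response and antigen presentation genes in microglia nuclei (library 2). With nuclei thinned, levels were 216 CPM and 140.0 CPM for Cdh5 in endothelial nuclei. Counts of members highest in their class were 1 for connexins and pannexins genes in endothelial nuclei (library 1), 2 and 1 for connexins and pannexins genes in astrocyte nuclei, 0 for NAD metabolism genes in endothelial nuclei (library 1), 3 for NAD metabolism genes in astrocyte nuclei (library 1), 1 and 1 for NAD metabolism genes in excitatory neuron nuclei, 4 for vascular basement membrane genes in endothelial nuclei (library 2), 3 for reactive astrocyte genes in astrocyte nuclei (library 2). Levels under about 5 UMIs per class, and classes of under 50 nuclei, are limited by depth.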

Other observations

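Connexin levels were set side by side in the 2 endothelial clusters; Gja4 and Gja5, the genes of connexins 37 and 40, and the cluster comparison were chosen after their values were seen. Cluster 30, led by Eln, Bmx and Mecom, held 18 nuclei of library 1 and 65 of library 2. In library 2, Gja5 stood at 77.0 CPM (16 UMIs, 44.0 to 125) in cluster 30 and at 1.14 CPM (1 UMI, 0.0289 to 6.36) in cluster 20, the larger endothelial cluster. Gjc1 went the other way, at 28.9 CPM (10.6 to 62.9) in cluster 30 and 162 CPM (137 to 191) in cluster 20. By markers, the second class of cluster 20 was pericytes with smooth muscle (mean fraction 0.403), and that of cluster 30 excitatory neurons (0.290). Whether pericyte RNA adds to the Gjc1 of cluster 20 was not tested. Gja4 stood at 33.7 CPM (7 UMIs, 13.5 to 69.4) in cluster 30 and 18.3 CPM (16 UMIs, 10.4 to 29.7) in cluster 20, with intervals that overlap. In library 1, Gjc1 stood at 57.0 CPM (3 UMIs, 11.8 to 167) in cluster 30 and 221 CPM (114 UMIs, 182 to 265) in cluster 20. Gja5 had 1 UMI in cluster 30 and 0 in cluster 20 there, and Gja4 0 and 10, too few in cluster 30 to compare. No other connexin was set side by side.

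Nnt, the mitochondrial transhydrogenase, had 23 UMIs in library 1 and 1 UMI in library 2, among 58108297 and 60547146. Ctsd, which encodes the lysosomal protease cathepsin D, had 4 and 3 UMIs. Whether the annotation, the strain or the counting keeps these counts low was not tested, so they do not show that the genes are not expressed.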
